A study of Mus musculus with 12 samples.

How the data were processed

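The iWAT libraries were made with the Illumina Stranded mRNA Prep Ligation kit after poly(A) selection, per the labels' protocols. The deposited table gives estimated counts per gene, 1 column per library, not scaled between libraries and not pooled. Between 9.53% and 11.1% of the values per library were not whole numbers, which is why they were treated as estimated counts. The quantifier of this table is not given in the sources used here. The submitters' processing notes for the whole series name fastp, featureCounts and the builds GRCm38 and GRCm39, without saying which belong to iWAT, so no coordinates are printed. Genes that share reads with a near-identical copy are uncertain, since how such reads were assigned is not given either.

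Estimated counts were rounded to whole numbers. Gene symbols came from GENCODE M21 names, which matched 26372 of 33200 gene identifiers (79.4%); identifiers without a symbol held 0.980% to 1.39% of the counts and stayed in the tests. Among tested genes sharing a symbol, lists used the one with the most counts. Library totals were 17970451, 20369345 and 20061936 counts in wild type and 18973117, 19668020 and 19783453 in KO. A single count corresponded to 0.0466 to 0.0574 CPM and a floor of 3 counts to 0.140 to 0.172 CPM. Intervals and floors cover counting error only. No 2 libraries held identical values.

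The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM normalization, filterByExpr on genotype, robust estimation, no covariate and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. Expression is given as TMM-normalised CPM, the counts of a gene scaled to a common library size, as mean ± SD, n = 3 per group. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Gene lists were written from textbook knowledge before the data were examined and tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Alternatives were DESeq2 1.42.0, limma-voom, other size factors, other filters, other thresholds, non-robust estimation, a replicate block and leaving out each library, on the same tested genes in the last case. Removing mitochondrial genes, an adjusted p of 0.10 and the extended muscle list were added after the data had been seen. The 4 nuclear genes removed with the mitochondrial ones matched mitochondrial transcripts at 99.8% to 100% identity.

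Named genes were chosen by a rule fixed before the data were examined. It takes Nrep, the 12 highest and 12 lowest log2 fold changes among named genes past the test with a mean of at least 2 CPM and no overlap between groups, and from each list up to 4 members past the test with the smallest adjusted p, or up to 2 members by mean CPM where none passed. Members of the sex, Nrep neighbour and substrain check lists may also be named.

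The tests were checked on counts simulated from the 6 libraries' means and dispersions for KO against wild type, with 200 of 16656 genes changed. The changed genes were drawn only from genes above a minimum mean CPM, so the recovery shares do not cover genes with few counts. On the 16403 genes kept, edgeR recovered 77% of 100 genes changed 2-fold and 97% of 100 changed 4-fold, with 10 false calls among 184. DESeq2 recovered 85% and 100% with 30 false calls among 215, and limma-voom 67% and 100% with 8 among 175. The simulation drew genes independently, so it holds no shared variation between animals. With 1 of 44 lists changed 2-fold, camera with either correlation and fry each called that list and 0 others.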

Results

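Inguinal white adipose tissue (iWAT), a subcutaneous fat depot, was profiled by poly(A) RNA sequencing in C57BL/6 wild-type mice and in mice carrying a global CRISPR/Cas knockout (KO) of Nrep, all fed a standard diet and 16 weeks old. The table held 3 wild-type and 3 KO libraries, described as biological replicates. Estimated gene counts summed to between 17970451 and 20369345 per library. The 6 liver samples of the series are not analysed here. The comparison asks which transcripts differ with genotype within iWAT.

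Nrep (ENSMUSG00000042834), the targeted gene, was nearly undetected in the KO tissue. The wild-type libraries held 1404, 1640 and 1300 Nrep counts, and the KO libraries held 2, 2 and 5. The mean fell from 71.1 ± 7.84 to 0.164 ± 0.0992 CPM (SD, n = 3 each), a log2 fold change of -8.72 (SE 0.268, adjusted p = 1.82e-05). The deleted part of the gene is not given in the sources used here, so the few remaining counts were not assigned to a part of it. None of the 11 tested genes from the list of Nrep neighbours passed the test over all genes in edgeR, while 1 passed in DESeq2 and 3 did without KO replicate 2. Adjusted over the list alone, 1 neighbour was higher and 1 lower: Epb41l4a had a log2 fold change of 0.82 and Dcp2 one of -0.49, each with a list-alone adjusted p = 0.0482 (over all genes in edgeR, adjusted p = 0.0991 and 0.102; past the test in 2 and 1 of 15 alternatives). The Y-linked gene Ddx3y lay between 61.6 and 103.5 CPM in all 6 libraries, and Xist, expressed from the inactive X chromosome, had 1 to 4 counts in each. Nnt, a gene that differs between C57BL/6 substrains, had 14.8 ± 6.32 CPM in wild type and 32.9 ± 8.36 in KO (SD, n = 3 each) without overlap, but did not pass the test (log2 fold change 1.15, edgeR adjusted p = 0.111; 0.00986 to 0.332 over the alternatives). This value is uncertain, because wild-type replicate 1 alone had 160.66 estimated counts on a second Nnt identifier beside 141.34 on the tested one. All other libraries had 0 there. On the tested identifier, wild-type replicate 1 had 7.50 CPM, wild-type replicates 2 and 3 had 18.9 and 17.9, and KO had 26.7 to 42.4. Counting both identifiers would raise wild-type replicate 1, and the combined value was not tested. Whether the groups share a substrain was not tested further.

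Among genes past the test, fat-synthesis, fat-storage and skeletal muscle genes were higher in the KO tissue. A chemokine receptor, a chemokine and a neutrophil-associated gene were lower. The fatty acid oxidation and lipolysis lists also had positive median log2 fold changes, with 0 members past the test. Of 16656 genes tested, 171 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 144 of them higher and 27 lower in KO. Of the 144 higher genes, 49 belonged to a skeletal muscle list that was extended after the calls were seen, which left 95 others. Scaling by library totals alone gave 129 higher and 49 lower genes and moved the median log2 fold change of all genes by -0.134. The calls depended on single libraries: 1 gene, Nrep, passed without wild-type replicate 1, wild-type replicate 2 or KO replicate 1, 3 passed without KO replicate 3, 334 without wild-type replicate 3 and 4221 without KO replicate 2. DESeq2 called 1774 genes and limma-voom 16 on the same 6 libraries, and the direction of all 171 genes was kept in both, which is not independent support.

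**Figure D1:**
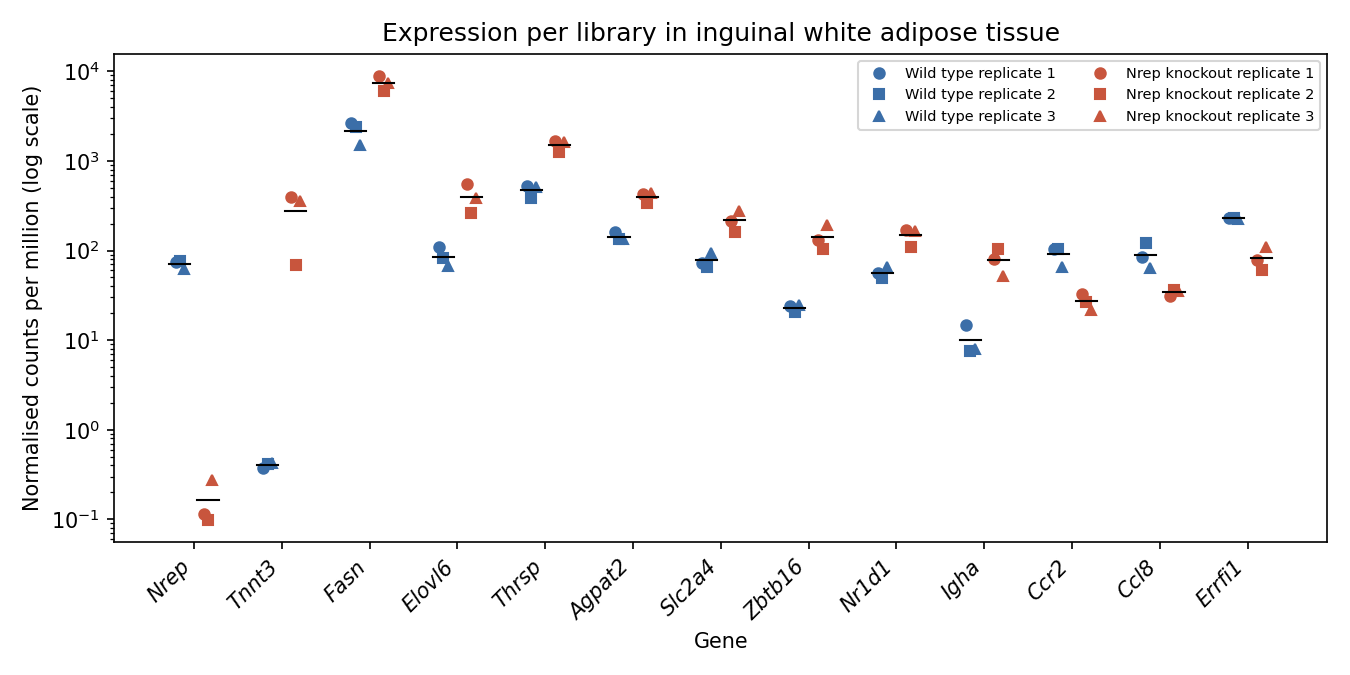
Normalised expression in CPM (log scale) of 13 named genes in each library, with wild-type libraries in blue, KO libraries in red, 1 marker shape per replicate and a bar at each group mean. Nrep lies at 62.1 to 76.5 CPM in the wild-type libraries and at 0.0985 to 0.278 CPM in the KO libraries.

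Genes for building fatty acids from acetyl-CoA rose in the KO fat, by up to 4.65-fold among the named ones. Of 20 tested members of the de novo lipogenesis list, 6 rose, none fell and 14 did not pass the test; adjusted over the list alone, 17 rose. Fasn, the fatty acid synthase, rose from 2178 ± 607 to 7424 ± 1374 CPM (SD, n = 3 each), a 3.41-fold difference (adjusted p = 0.0458). Elovl6, which elongates palmitate, rose 4.65-fold (log2 fold change 2.22, SE 0.303, adjusted p = 0.0370). Thrsp, a lipogenic regulator, rose 3.21-fold from 473 ± 76.6 to 1518 ± 221 CPM (adjusted p = 0.0280), and Slc25a1, the mitochondrial citrate carrier, rose 2.62-fold (adjusted p = 0.0435). The list's median log2 fold change was 1.14, and camera gave an adjusted p of 3.25e-22 with the preset correlation. With an estimated correlation, camera gave adjusted p = 0.374 (0.0261 unadjusted), a value that the adjustment gave to many lists alike. Without wild-type replicate 1 or 2, or KO replicate 1 or 3, 0 members passed; without wild-type replicate 3, 4 did, and without KO replicate 2, 17. The log2 fold changes moved less than the calls: over 15 alternatives Fasn lay at 1.56 to 1.95, Elovl6 at 1.92 to 2.50 and Thrsp at 1.54 to 1.86, and they passed in 9, 10 and 11 of them.

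Among the genes of triglyceride assembly and fat uptake, 3 of 18 and 1 of 12 tested members rose and none fell. Agpat2 and Dgat2, acyltransferases of triglyceride synthesis, rose 2.80-fold (adjusted p = 0.0258) and 2.72-fold (adjusted p = 0.0326). Pnpla3, a lipid droplet protein, rose 2.02-fold from 36.2 ± 4.99 to 73.1 ± 7.52 CPM (adjusted p = 0.0370). These were the called members of the triglyceride list; adjusted over the list alone, 14 rose. The triglyceride list had an adjusted p of 1.02e-13 with the preset correlation and adjusted p = 0.374 with an estimated correlation. Gpihbp1, which anchors lipoprotein lipase to capillaries, rose 2.33-fold (adjusted p = 0.0485) as the called member of the fatty acid uptake list. That list had a median log2 fold change of 0.80 and an adjusted p of 6.78e-08 with the preset correlation, and adjusted p = 0.374 with an estimated correlation. Slc2a4, the insulin-responsive glucose transporter, rose 2.80-fold from 77.8 ± 14.96 to 217.8 ± 56.2 CPM (adjusted p = 0.0435). It was the 1 called member of 18 mature adipocyte markers, whose median log2 fold change was 0.85; the list's adjusted p was 3.14e-10 with the preset correlation and adjusted p = 0.374 with an estimated correlation. The adipocyte marker level was 0.26 in KO replicate 2, close to 0.24 in wild-type replicate 3, and 0.88 and 1.12 in KO replicates 1 and 3. Over all tested genes, which are not independent replicates, KO replicate 2 had a Pearson correlation of log2 CPM of 0.980 with wild-type replicate 3 and 0.978 with KO replicate 1, and its score on the first principal component was -0.724, against -46.5 to -20.3 in wild type and 43.0 and 61.6 in the other KO libraries. Rbp4, a retinol carrier secreted by fat, rose 2.23-fold (adjusted p = 0.0476).

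Genes of pyruvate oxidation and sterol synthesis also rose. Pdhb and Dlat, subunits of the pyruvate dehydrogenase complex, rose 2.31-fold (adjusted p = 0.0390) and 2.05-fold (adjusted p = 0.0437), as 2 of 20 tested members of the tricarboxylic acid cycle list; adjusted over the list alone, 19 rose. That list had an adjusted p of 1.20e-15 with the preset correlation and adjusted p = 0.374 with an estimated correlation. Insig1 and Lss, of sterol regulation and synthesis, rose 1.77-fold (adjusted p = 0.0466) and 1.84-fold (adjusted p = 0.0474), as 2 of 22 members of the cholesterol list. Lists of fat and amino acid breakdown had positive medians too, with 0 members past the test. The lipolysis level overlapped between the groups, at 0.12 in KO replicate 2 and 0.14 in wild-type replicate 3. In the same 2 libraries the fatty acid oxidation level was 0.32 and 0.24, and the branched-chain amino acid level 0.24 and 0.20. The fatty acid oxidation, lipolysis and branched-chain amino acid catabolism lists had median log2 fold changes of 0.77, 0.76 and 0.67. Adjusted over the list alone, 17 of 21, 8 of 16 and 16 of 18 members rose, and 1 fatty acid oxidation gene fell. In camera each had adjusted p = 0.374 with an estimated correlation. Of 70 tested oxidative phosphorylation genes, 0 passed over all genes in edgeR, 63 passed in DESeq2 and 68 rose when adjusted over the list alone. Their median log2 fold change was 0.60, with adjusted p = 1.66e-31 with the preset correlation and adjusted p = 0.374 with an estimated correlation. The oxidative phosphorylation level was 0.60, 0.37 and 0.76 in KO replicates 1, 2 and 3. In the same libraries the adipocyte marker level was 0.88, 0.26 and 1.12, and the skeletal muscle level 6.50, 3.98 and 6.73. Whether adipocyte or muscle RNA accounts for the higher oxidative phosphorylation values was not tested. Mitochondrially encoded genes held 5.08% ± 1.65 of wild-type and 7.93% ± 1.46 of KO counts (SD, n = 3 each; exact permutation p = 0.2, two-sided, the smallest possible being 0.1).

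**Figure D2:**
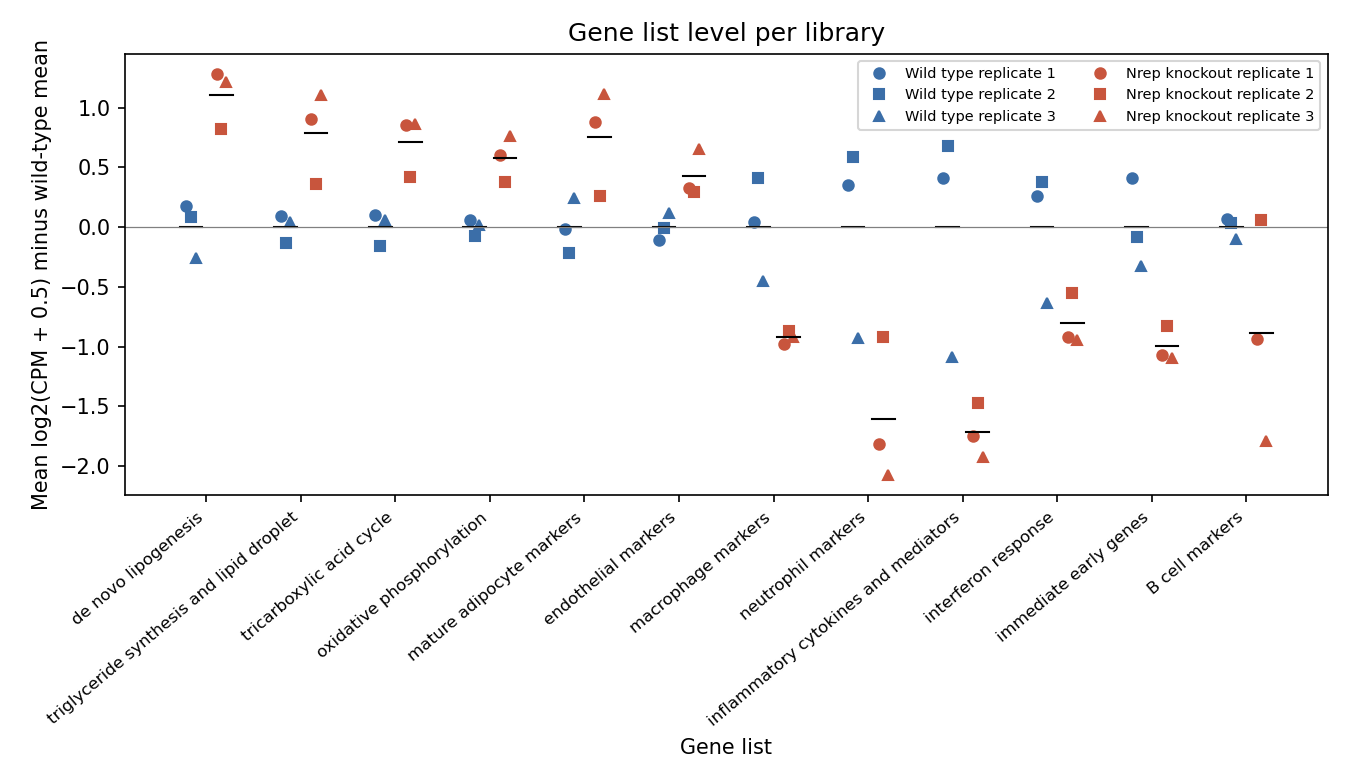
Level of 12 gene lists in each library, as the mean over members of log2(CPM + 0.5) minus the wild-type mean, with wild-type libraries in blue, KO libraries in red, 1 marker shape per replicate and a bar at each group mean. The lipogenic list lies at 0.82 to 1.28 in the KO libraries, and the inflammatory list lies at 0.41, 0.68 and -1.09 in wild-type replicates 1, 2 and 3.

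Skeletal muscle transcripts were present in all 3 KO libraries and nearly absent from the wild-type ones. The muscle list took 0.424%, 0.0823% and 0.397% of the counts of KO replicates 1, 2 and 3, and 0.00531% ± 0.000104 of wild-type counts (SD, n = 3). Of 15 tested members 11 rose and none fell; adjusted over the list alone, all 15 rose. Tnnt3, a fast-fibre troponin, rose from 0.407 ± 0.0307 to 276 ± 180 CPM (log2 fold change 9.38, SE 0.842, adjusted p = 0.0187), and Atp2a1, the calcium pump of fast fibres, rose from 0.496 ± 0.123 to 369 ± 257 CPM (adjusted p = 0.0207). Ckm, the muscle creatine kinase, had 3, 0 and 1 counts in wild type and 9879, 1993 and 8749 in KO. Myh4, a fast myosin heavy chain, had 3 counts in all wild-type libraries together and 30667 in KO, a ratio of 11219 with a 95% exact counting interval of 3838 to 54403. Among genes past the test with a gene name beyond a predicted-gene number, a mean of at least 2 CPM over the 6 libraries and no overlap between groups, the others with the largest positive fold changes were Pvalb, Tcap, Tnnc2, Myoz1, Xirp2, Eef1a2, Actn3 and Mylpf, all expressed in muscle. The list had an adjusted p of 3.39e-46 with the preset correlation and adjusted p = 0.374 with an estimated correlation. Without wild-type replicate 1 or 2, or KO replicate 1 or 3, 0 members passed; without wild-type replicate 3, 10 did, and without KO replicate 2, 15. Over 15 alternatives the log2 fold change of Myh4 lay at 12.77 to 14.22 and that of Tnnt3 at 8.98 to 9.89, and each passed in 10 of them.

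Several genes of myeloid and mast cells fell in the KO tissue. Ccr2, the receptor that recruits monocytes, fell from 90.9 ± 22.6 to 27.05 ± 5.57 CPM (SD, n = 3 each; log2 fold change -1.75, SE 0.229, adjusted p = 0.0326). Ccl8, a chemokine, fell from 89.6 ± 28.9 to 34.3 ± 2.77 CPM (adjusted p = 0.0458) and was the 1 called member of 20 in the inflammatory list. Retnlg, a neutrophil-associated resistin-like gene, fell from 7.78 ± 2.91 to 1.16 ± 0.609 CPM (adjusted p = 0.0469), as 1 of 11 neutrophil markers. Mcpt4, a mast cell protease, fell from 42.1 ± 3.79 to 21.5 ± 1.90 CPM (adjusted p = 0.0326), and Mrgprb1, a mast cell receptor, fell with a log2 fold change of -1.41 (adjusted p = 0.0468). The inflammatory list had a median log2 fold change of -2.10 and an adjusted p of 5.22e-11 with the preset correlation, and adjusted p = 0.374 with an estimated correlation. Adjusted over the list alone, 16 of its members fell and 1 rose. Its level in wild-type replicate 3 was -1.09, against 0.41 and 0.68 in wild-type replicates 1 and 2 and -1.92 to -1.47 in the KO libraries. Of 15 macrophage markers 0 passed over all genes in edgeR and 8 in DESeq2, while 10 fell when adjusted over the list alone; Lyz2 had 1979 ± 384 CPM in wild type and 1156 ± 292 in KO. The macrophage list had an adjusted p of 1.85e-08 with the preset correlation and adjusted p = 0.374 with an estimated correlation. The B cell marker level was 0.06 in KO replicate 2 and -0.93 and -1.79 in KO replicates 1 and 3. Among genes past the test with a gene name beyond a predicted-gene number, a mean of at least 2 CPM over the 6 libraries and no overlap between groups, the others with the largest negative fold changes were Ccn5, Anxa8, Gnal, Errfi1, Ppl, Gpr65 and Gas7, with log2 fold changes of -2.48, -1.54, -1.52, -1.47, -1.44, -1.31 and -1.20. Larger negative values did not pass, as in Ccl7, a chemokine named after its values were seen, with 92.1, 105.0 and 6.64 CPM in wild-type replicates 1, 2 and 3 and 1.28 to 2.07 CPM in KO (log2 fold change -5.42, edgeR adjusted p = 0.0547).

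Of 14 tested genes that respond to glucocorticoids, 2 rose and 1 fell, and of 18 circadian clock genes 1 rose and none fell. Zbtb16 and Fkbp5, glucocorticoid-induced genes, rose 6.18-fold (23.0 ± 1.99 to 142.4 ± 46.0 CPM, adjusted p = 0.0187) and 2.41-fold (adjusted p = 0.0280), and Errfi1 fell from 228 ± 4.61 to 82.4 ± 24.2 CPM (adjusted p = 0.0390). The other 11 of 14 members did not pass, and the list as a whole had an adjusted p of 0.653 with the preset correlation and adjusted p = 0.881 with an estimated correlation. In fry's mixed test, which asks whether members change in either direction, its adjusted p was 0.000560. Its median and mean log2 fold changes were negative, at -0.17 and -0.06, while camera's direction was up. Nr1d1, a repressor in the circadian clock, rose 2.63-fold from 56.6 ± 8.01 to 148.7 ± 33.5 CPM (adjusted p = 0.0390), as the called clock gene in edgeR, where DESeq2 called 12. The clock list had an adjusted p of 0.000416 with the preset correlation and adjusted p = 0.374 with an estimated correlation. Fosl2, an AP-1 transcription factor, fell with a log2 fold change of -0.64 (adjusted p = 0.0476), as the 1 called member of 17 tested immediate early genes, which are induced rapidly by stimulation or stress. All 17 had negative log2 fold changes and 11 fell when adjusted over the list alone; the list had an adjusted p of 6.51e-09 with the preset correlation and adjusted p = 0.374 with an estimated correlation. Its level was 0.41, -0.08 and -0.32 in wild-type replicates 1, 2 and 3 and -1.09 to -0.83 in the KO libraries, and so it was lower in KO alongside the inflammatory list. Igha, the constant region of IgA, rose 7.82-fold from 10.1 ± 4.03 to 79.1 ± 26.1 CPM (adjusted p = 0.0280), a value that is uncertain where reads are shared between immunoglobulin genes.

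Across the 44 lists with at least 5 tested members, 36 passed an adjusted p of 0.05 in camera with the preset correlation, 17 up and 19 down. None passed with an estimated correlation, where 2 had an unadjusted p under 0.05, skeletal muscle (0.0139) and de novo lipogenesis (0.0261). None passed in fry's directional test, where 20 had an unadjusted p under 0.05. The smallest adjusted p-values of these 2 tests were 0.374 and 0.104. In camera, lists that share 0.374 differed in unadjusted p, as with 0.0959 for oxidative phosphorylation and 0.198 for the clock list. In fry's mixed test 15 of the 44 lists passed. The estimated correlation was 0.47 for de novo lipogenesis, 0.73 for oxidative phosphorylation and 0.92 for skeletal muscle, against the preset of 0.01. It was negative for epithelial and mural cell markers, at -0.08 and -0.05. Where the estimate is far above the preset, camera's p-values with the preset correlation overstate the evidence.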

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

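Settings chosen after the data had been seen were the adjusted p of 0.10, the removal of mitochondrial genes and the extended muscle list. The Nrep call held in every alternative run, with log2 fold changes of -9.31 to -8.39. The count of 171 genes (144 higher, 27 lower) did not hold. DESeq2 gave 1774 (1188 and 586), limma-voom 16 (15 and 1), and no filter 1370 (928 and 442), where the median prior degrees of freedom rose from 3.88 to 46.9. An adjusted p of 0.01 left 1 gene (0 and 1), and 0.10 gave 1378 (920 and 458). Library totals alone gave 49 lower genes, and leaving out the extended muscle list left 95 higher genes. Leaving out 1 library gave 1 to 4221 genes, 0 to 2410 higher and 1 to 1811 lower; these fits hold fewer samples, and why KO replicate 2 moves the count most was not tested. Direction was kept for all 171 genes in every fit that tested them. These fits reuse the libraries in which the genes were called, so a kept direction is not independent support. Of the 44 named genes past the test besides Nrep, 44 passed in DESeq2, 6 in limma-voom and 0 without wild-type replicate 1, wild-type replicate 2 or KO replicate 1. Of the 36 lists, 0 passed with an estimated correlation and 0 in fry's directional test, while fry's mixed test, which ignores direction, passed 15 of the 44; the other settings gave 31 to 39. For the other changed counts the cause was not tested.

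With the replicate number as a block the counts were 1225 genes, 790 higher and 435 lower. The labels give no shared litter or day, and the deviations of same-numbered libraries correlated at -0.01, 0.22 and 0.11 for replicates 1, 2 and 3, so the numbers were not taken to pair the samples. Not every library correlated best with its own number: wild-type replicate 3 correlated at 0.18 with KO replicate 1.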

Other observations

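Blood vessel markers were higher in value in the KO tissue. All 13 tested endothelial markers had positive log2 fold changes, with a median of 0.42; 0 passed over all genes in edgeR and 8 rose when adjusted over the list alone. Cdh5, an endothelial junction protein, had 217 ± 11.9 CPM in wild type and 315.5 ± 46.2 in KO (SD, n = 3 each; adjusted p = 0.0965). The list had an adjusted p of 3.96e-05 with the preset correlation and adjusted p = 0.374 with an estimated correlation. Prx, a periaxin gene of Schwann cells, rose 1.62-fold (adjusted p = 0.0499).

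The endoplasmic reticulum list had lower values in all KO libraries, and the matrix list overlapped between the groups. Of 20 unfolded protein response genes 17 had negative log2 fold changes and 0 passed over all genes; Hspa5, the main chaperone of that compartment, had 709 ± 152 CPM in wild type and 429 ± 25.9 in KO (SD, n = 3 each; edgeR adjusted p = 0.0879). Of 28 collagen and matrix genes 25 were negative and 0 passed; Col3a1 had 4356 ± 565 and 2720 ± 937 CPM (edgeR adjusted p = 0.204). Adjusted over the list alone, 9 unfolded protein response genes fell and 0 matrix genes passed, and the matrix level was -0.11 in KO replicate 3 and -0.35 in wild-type replicate 3. Both lists passed with the preset correlation, at adjusted p-values of 4.18e-04 and 2.20e-04, and had adjusted p = 0.374 and adjusted p = 0.451 with an estimated correlation.

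Apart from the splits of the libraries, the tests below were chosen after the results had been seen. With 3 libraries per group there are 10 splits, too few for a share under 0.05. The real split gave 171 genes, 144 in the larger and 27 in the smaller direction, and 36 lists, and 1 split reached each of these. The highest of the other splits gave 0, 0 and 0 genes and 31 lists, and the lowest gave 8 lists. Lists thus passed with the preset correlation in every split.

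The muscle transcripts may come from skeletal muscle carried over with the fat pad; muscle of 1 kind would give all members 1 ratio between KO libraries, but the SD over 15 members of the log2 ratio of KO replicate 2 to the mean of the other two was 1.12, above the bound of 1 set for it, which argues against muscle of a fixed composition. Myh1 and Mb stood apart, at ratios of 0.0177 and 0.0271 against a median of 0.183 (named after their values were seen), so a further test was added on 7 oxidative and slow fibre genes outside the list. Their median log2 ratio of KO replicate 1 to KO replicate 3 was -3.50, where differing fibre types needed one under -1. Myh1 and Mb themselves had -2.14 and -2.75 in this comparison. That comparison leaves out KO replicate 2, so it does not by itself account for the SD of 1.12. In KO replicates 1, 2 and 3, Myh2 had 51, 3 and 735 counts, Myh7 had 8, 0 and 99, and Myl2 had 5, 0 and 68. Tnnc1 had 2, 0 and 21, and Myl3 had 14, 7 and 64. Tnnt1 and Tnni1 had more counts in KO replicate 2 than in KO replicate 1, with 18, 23 and 73 for Tnnt1. Counts were low, at 2 to 51 per gene in KO replicate 1. Tnni1 had 22 counts over the wild-type libraries together and 3, 10 and 47 in KO replicates 1, 2 and 3. The values show more of these transcripts in KO replicate 3 than in KO replicate 1, and differing fibre type stays open. A myogenic programme in the fat pad stays open and cannot be told apart from carry-over by these counts: 0 of 8 early myogenic genes had enough counts to be tested. Summed over each group, wild type and KO had 0 and 9 counts of Myog and 0 and 15 of Myod1, both myogenic regulators, and 2 and 3 of Myh3 and 5 and 7 of Myh8, the embryonic and perinatal myosins, against 3 and 30667 of the adult myosin Myh4; the other 4 genes had at most 6 counts in either group.

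For the higher lipogenic genes, 3 candidate explanations besides genotype were examined, and genotype itself stays open as untested. Other differences between the groups, such as litter or day, are not given in the labels and were not examined. Carried-over muscle is argued against, because the lipogenic list gained at least 7.54 times as many CPM as the muscle list in each KO library. A larger share of adipocyte RNA cannot be told apart: the lipogenic minus the adipocyte marker level was 0.36 higher in KO (SD 0.44 in wild type and 0.23 in KO, n = 3 each, exact permutation p = 0.3, two-sided), with overlapping libraries. Another time of day at collection also cannot be told apart from genotype. The mean log2 fold changes of 9 clock genes of 1 phase and 4 of the opposite phase differed by 2.16. Another feeding state at collection stays open too, since the clock contrast does not measure feeding. Dbp and Arntl, named after their values were seen, had log2 fold changes of 1.55 and -1.26 (edgeR adjusted p = 0.0570 and 0.0765).

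The lower inflammatory values rest largely on wild-type replicates 1 and 2. Ccl2, named after its values were seen, had 87.6, 103.1 and 4.83 CPM in wild-type replicates 1, 2 and 3 and 1.28 to 2.56 CPM in KO (edgeR adjusted p = 0.0625). Differing lymph node content is argued against as the source of the inflammatory spread within wild type. There the B cell markers spanned 0.0962 times the span of the inflammatory list, and within KO the inflammatory list spanned 0.245 times that of the B cell markers. Spans cannot show whether lymph node content adds to the difference between groups. The lymph node stroma level was -0.68, -0.07 and -1.31 in KO replicates 1, 2 and 3, and -0.03 to 0.05 in wild type. Equal dilution of all other cells by adipocyte RNA is argued against as the only cause. The endothelial minus the inflammatory level was 2.14 higher in KO, with no overlap between groups (exact permutation p = 0.1, two-sided, the smallest possible). The endothelial and mural levels averaged 0.42 and 0.12 in KO. The T and NK cell, dendritic cell and mast cell levels averaged -0.41, -0.49 and -0.67. The T and NK cell level was -0.51, 0.37 and -1.09 in KO replicates 1, 2 and 3, and the dendritic cell level -0.43, 0.04 and -1.07. In KO replicate 2 both were above every wild-type library, so of these levels only the mast cell level was lower in all KO libraries. A contribution of dilution is not excluded by these values. Variation between wild-type animals stays open: the inflammatory level ranged over 1.77 within wild type, and the gap from the lowest wild-type to the highest KO library was 0.379.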
